A study of Mus musculus with 10 samples.

How the data were processed

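Gene expression was measured on 10 Illumina mouse bead arrays, 1 per RNA sample, in macrophages of 6 tissues and in bone marrow-derived macrophages (BMDM). Per the labels' protocols, RNA was purified on micro columns with a DNase step and amplified to biotin-labelled cRNA. The deposited signal table holds, per the file headers, a signal and a detection p-value for each of 46632 probes on each array. The signals are linear intensity, as deposited, without normalization between arrays or background subtraction. The detection p-value of the deposited table moves in steps of 1 in 1603, the number of negative controls this implies. The series values of the authors are linear intensity with medians between 118.1 and 118.3 and the same lowest (83.43) and highest (42859) value on every array, so they appear to be quantile normalized; the method is not given in the sources used here. Each column of the authors' values correlated best with the signal column of the same sample (r between 0.996 and 1). Every per-sample column was used, so 0 were left out.

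Signals were background corrected from the detection p-values, quantile normalized and put on the log2 scale with neqc (limma 3.58.1, R 4.3.3, offset 16). Of the probes, 29976 carried 1 gene symbol, 10 several and 16646 none, and 29921 had a gene identifier found in the mouse gene table (GRCm38.p6), which was used for names and for the X and Y chromosomes. A gene was represented by its probe with the highest mean, and a probe without a single symbol stood for itself. Transcripts with a detection p under 0.01 on at least 1 array were tested, which left 12845 (9171 named genes and 3674 unnamed probes) from 17711 named genes on the array. Depth was read as the share of probes detected, 22.6% to 26.4% per array. Where all arrays of a group missed a gene, folds were computed against the lowest normalized value among detected probes of each array and are given as bounds.

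Arrays were grouped by the tissue in their labels. A single limma model with 1 mean per group and empirical Bayes variances was fitted, with 3 residual and 4.02 prior degrees of freedom, a prior SD of 0.188 and a median residual SD of 0.185 on the log2 scale. The F test asked for any difference among groups. A transcript was higher in a group than in every other group when it passed the test against each of the other 6, by the largest of the 6 p-values, with at least a 2-fold difference over the next-highest group and detection on every array of the group. Each tissue was compared with BMDM, and BMDM with the equally weighted mean of the 6 tissues. In the text, list results are given for each group's own identity list for every function and stress list that passed, and for every other-cell list that was up, or that was down and stayed down without the groups where it was up in the mean (1 list was up in no group). Gene lists were written from general knowledge before the data were examined and tested with camera (limma) against all other transcripts, each group against the mean of the other 6, with a preset correlation of 0.01 and with an estimated one. P-values were adjusted by Benjamini and Hochberg's method over all transcripts, or over the 266 list tests, with a threshold of 0.05.

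Genes were named by a rule written before the data were examined. It took up to 8 genes per group with the largest difference over the next-highest group and with each array of the group above all others. It took the 12 highest and 12 lowest changes of BMDM against the tissues with BMDM outside the range of all 9 tissue arrays. It took up to 4 members per described list with the largest differences among those past the threshold, and any lineage regulator or pan-macrophage gene. Genes known only by clone or number were counted and not named. Sex-linked genes, Adipoq and the per-array levels of haemoglobin genes were chosen after their values were seen.

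The same model was tested on simulated data with 12845 transcripts, of which 200 were changed by 1, 2 or 3 on the log2 scale. Noise for every array was drawn from the residual SDs of the fit. The assumption that groups with 1 array vary like the others was thus built in and not tested. In the data 79.6% of transcripts differed among the groups, so the recoveries and false calls below need not carry over. For transcripts higher in the alveolar group, with 1 array, 5.97%, 68.7% and 92.4% of the changes of those sizes were recovered, with 0 false calls among all transcripts. For the peritoneal group, with 2 arrays, it recovered 8.96%, 76.1% and 95.5%, also with 0 false calls. For BMDM against the mean of the tissues it recovered 34.3%, 88.1% and 97%, with 2 false calls. With a simulated array-set effect of the size seen between the peritoneal arrays, the same model recovered 0%, 37.3% and 81.8% for the alveolar group, 0%, 56.7% and 92.4% for the peritoneal group and 1.49%, 73.1% and 97% for BMDM against the tissues. With array set as a block on those data, recovery was 0% at all 3 sizes for the alveolar group and 0%, 49.3% and 80.3% for the peritoneal group. The F test recovered 0%, 37.3% and 71.2% without a set effect and made 0 calls with one, blocked or not.

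The comparisons, tests, lists and most alternatives were set before the data were examined. These alternatives were the authors' values, no background correction, median scaling, no filter or detection on at least 2 arrays, variance trend with robust fitting, the mean of a gene's probes, a replicate block, each replicated array left out, other fold minimums and the estimated correlation. An array-set block, a fit without the BMDM array and, for lists of other cell types that fell, a mean without the groups where that list was up were added after the data were seen. A slide block was not run, because the file names no slides. No mapping to the genome was used.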

Results

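Macrophages from 6 mouse tissues and macrophages grown in culture from bone marrow were compared for gene expression on Illumina bead arrays, which measure labelled RNA with gene-specific probes. The labels describe the mice as male C57BL/6, an inbred strain, and the cells as untreated. The 10 arrays fell into 7 groups. Peritoneal, small intestinal and adipose tissue macrophages had 2 arrays each, and 1 array each was given to alveolar macrophages (from the lung), Kupffer cells (the macrophages of the liver), splenic red pulp macrophages and bone marrow-derived macrophages (BMDM). The BMDM had been cultured for 7 days with M-CSF, the growth factor on which macrophages depend. The labels do not say whether the 2 arrays of a group came from separate animals, so every p-value measures the spread between these arrays, which may be technical. The 4 groups with 1 array had no replicates, and they were assumed to vary like the other 3. The number of arrays limits the precision.

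Between 10537 and 12305 probes (22.6% to 26.4%) were detected per array. The median raw signal separated the arrays into 2 sets. It lay between 89.83 and 107.9 in the dimmer set of 5 arrays (peritoneal replicate 1, alveolar, Kupffer, splenic and BMDM) and between 135.7 and 166.5 in the brighter set of 5 (peritoneal replicate 2, both intestinal and both adipose arrays). The peritoneal group was the only one with an array in each set, so any adjustment for the sets rests on that pair. With the sets as a block, the residual spread comes from the intestinal and adipose pairs alone. A larger count with the block therefore does not show that a result is free of the set. Across detected transcripts, which are not independent replicates, the paired arrays of a group correlated at r = 0.995 in the intestine, 0.994 in adipose tissue and 0.975 in the peritoneum, where the arrays came from different sets. The SD of the log2 difference between the arrays of a group was 0.228, 0.244 and 0.52 in the same order. Arrays of different groups correlated between 0.77 and 0.902. Of the group means, intestinal and adipose macrophages were the most alike (r = 0.903), followed by Kupffer cells and splenic macrophages (r = 0.898), and splenic macrophages and BMDM were the least alike (r = 0.77); each of these pairs lies within 1 set.

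**Figure D1:**
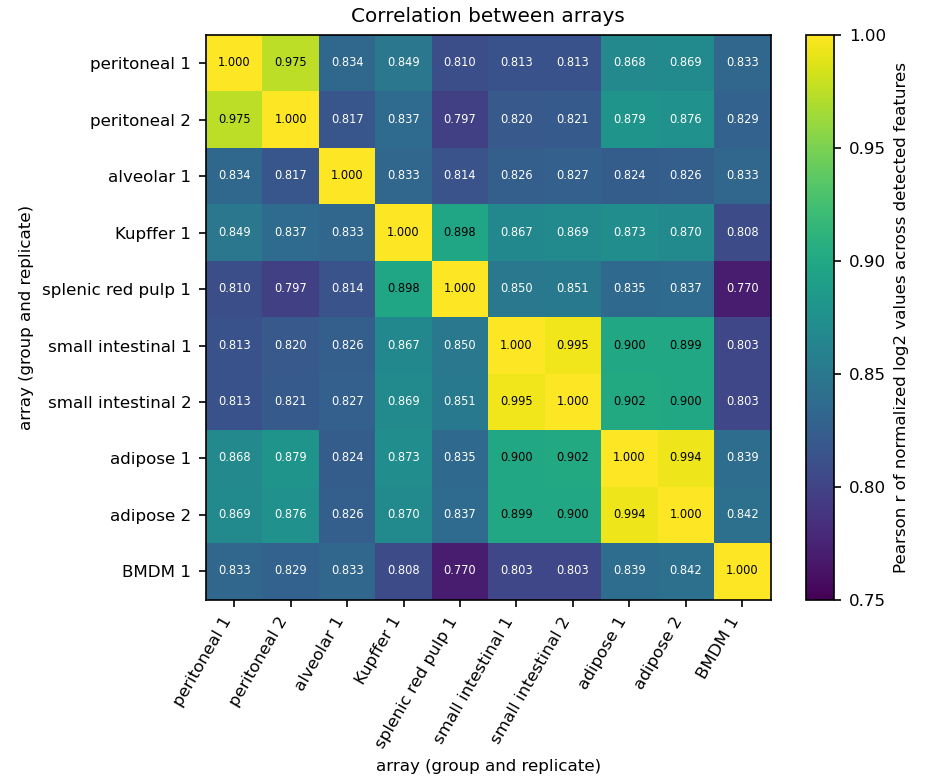
Pearson correlation of normalized log2 values between each pair of the 10 arrays across detected transcripts, with groups and replicates on both axes. The 3 pairs of replicate arrays lie between 0.975 and 0.995, above every pair of different groups (0.77 to 0.902).

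The first comparison asked which transcripts differed among the 7 groups. A transcript here is a gene, represented by its brightest probe, or a probe without a gene symbol. Of 12845 tested transcripts, 10219 (79.6%, 7251 of them named genes) differed among the groups (limma F test, adjusted p under 0.05). With array set as a block the number was 11499, of which 10022 were shared. Most general macrophage genes were present throughout: 18 of the 19 pan-macrophage genes tested were detected in all 7 groups. Their levels differed nevertheless, as 19 of the 19 passed the F test. Camk1, also on that list, was detected on no array and was not tested. The narrowest ranges between group means, on the log2 scale, were those of Fcer1g, a signalling chain of Fc receptors (0.89), and Lamp1, a lysosomal membrane protein (0.90). The widest were those of Cd63 (5.977) and Aif1 (5.455). Itgam, the integrin chain CD11b, was the tested gene not detected in every group. It was highest in peritoneal macrophages (9.88 ± 0.32, SD, n = 2), lay at 7.46 in BMDM, and was not detected in alveolar macrophages, Kupffer cells or splenic macrophages. Lyz2, the lysozyme of myeloid cells, was at 10.26 in the spleen against 14.21 to 15.33 in the other groups. As a list, the pan-macrophage genes passed the test in 0 of 7 groups (limma camera, lowest adjusted p = 0.052, in Kupffer cells, and 1 group at an unadjusted p under 0.05), and in Kupffer cells alone with array set as a block (adjusted p = 0.0232).

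Of 29 lineage regulators tested, 28 differed among the groups and 5 were at least 2-fold higher in a single group than in every other. These were Gata6 and Rarb, a retinoic acid receptor, in peritoneal macrophages, Spic in the spleen, Id3 in Kupffer cells and Egr2 in alveolar macrophages. Spic, a transcription factor of iron-recycling macrophages, was at 12.09 in the spleen and 8.68 in Kupffer cells, a difference of 3.42 (adjusted p = 0.002). Id3 reached 12.07 in Kupffer cells against 9.43 in BMDM, the next-highest group (adjusted p = 0.00217). Nr1h3, the oxysterol receptor LXR alpha, stood at 13.91 in Kupffer cells and 13.82 in the spleen, which did not differ past the threshold. Pparg, a lipid-sensing nuclear receptor, was at 11.72 in alveolar and 11.32 in splenic macrophages and was not detected in peritoneal macrophages. Maf was not detected in alveolar macrophages and ranged from 8.43 to 12.13 elsewhere. Bhlhe40 was at 6.04 ± 0.05 (SD, n = 2) in adipose macrophages against 9.30 to 12.29 in the other groups.

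The next comparisons asked which transcripts set each macrophage population apart from the other 6 groups. A transcript was counted when it was detected on every array of its group, passed the test against each other group and was at least 2-fold above the next-highest. The counts within an array set, given below, therefore largely follow from this rule and do not test the array set. For a group with 1 array, all in the dimmer set, only peritoneal replicate 1 could break the 2-fold margin there. Where a group had no array that detected a gene, its level is a bound, taken per array as the lowest normalized value among detected probes, and the fold is given as at least that size. Gene lists were compared between each group and the mean of the other 6 with limma camera, and a list member is said to have risen or fallen by the same contrast. In 38 lists and 7 groups, 113 of 266 tests passed (44 up and 69 down) with the preset correlation of 0.01 between genes, and 115 did with array set as a block (106 shared). With a correlation estimated from the data, 0 of the 113 calls held in camera (lowest adjusted p = 0.187), although 63 of the 266 tests had an unadjusted p under 0.05. That setting also rests the camera test on the 3 residual degrees of freedom of the fit. The alveolar identity list had an estimated correlation of 0, below the preset one, yet its unadjusted camera p went from 1.11e-13 to 0.00422. The lost calls therefore cannot be put down to correlation between genes alone. Where no count adjusted over the list alone is given, it was the same as the count over all transcripts. Of 91 list results followed through the alternatives, 85 kept their call with array set as a block. A difference from the mean of the other 6 groups includes the rise or fall of each of them. The cell cycle and cholesterol biosynthesis lists were up in both alveolar macrophages and BMDM, which lowers the other groups against that mean. Falls of these lists were retested without the BMDM array, but not without the alveolar array. In 24 results a list of another cell type fell, and for the 23 whose list was up in another group the test was therefore repeated, after the results were seen, with the groups where that list was up left out of the mean. It still passed in 6 of the 23 (0 of them with an estimated correlation, lowest adjusted p = 0.463, 1 at an unadjusted p under 0.05 in camera), and those 6 are described below, with the adipocyte list in the intestine, which was up in no group. The hepatocyte list, lower in all 6 groups other than Kupffer cells, was not among them: without Kupffer cells its medians lay between -0.10 and 0.04. The identity lists came from general knowledge of published macrophage profiles, which may include these same arrays, so their counts are not independent evidence of direction. Detection in the own group alone was enough for a member to be tested, which favours a high share. Of the identity genes on the array, 14 of 20 alveolar, 15 of 18 splenic, 19 of 20 Kupffer and 19 of 20 intestinal ones were tested. The others were detected on no array. All 21 peritoneal and all 19 adipose ones were tested. Probes for close gene families, such as the Serpina1, Defa, Cd209, Ear, haemoglobin and H2 genes, can share sequence, and which member they measured is uncertain.

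**Figure D2:**
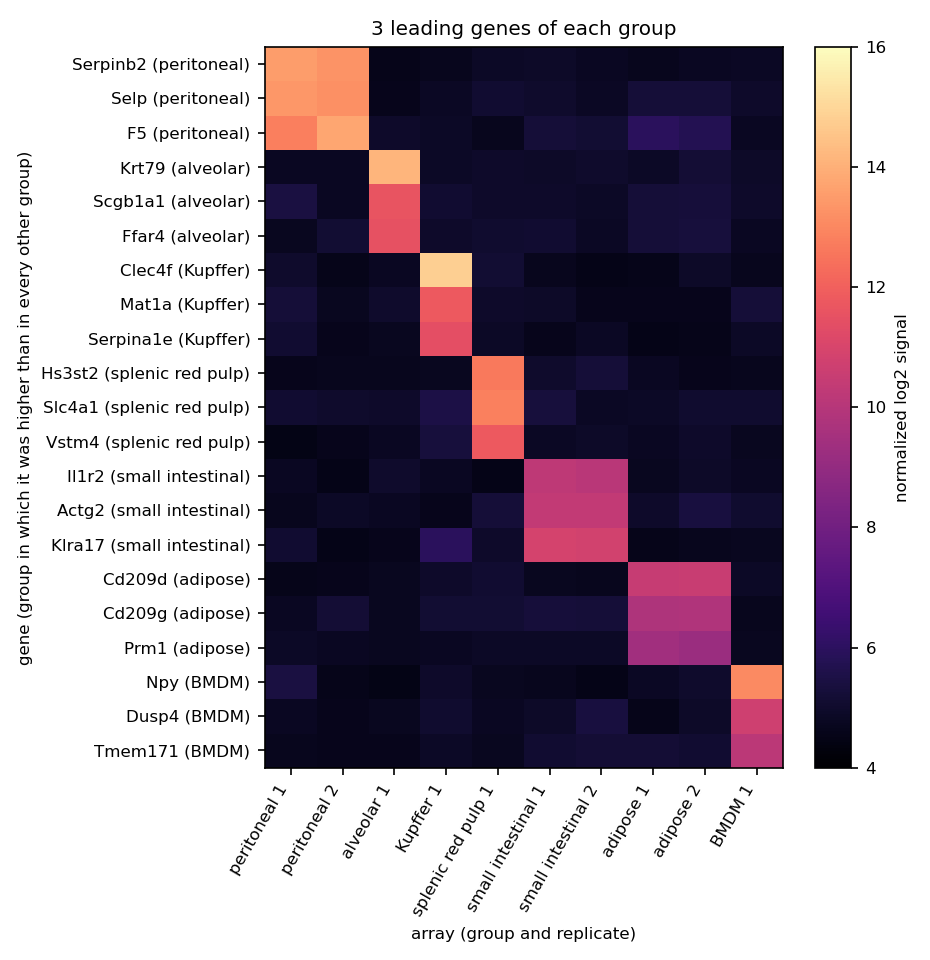
Normalized log2 signal on each of the 10 arrays (columns) for the 3 genes per group with the largest fitted difference over the next-highest group (vertical axis, with the group in brackets). Signals in the own group run from 9.33 (Prm1 mean) to 14.81 (Clec4f), and the genes lie near the floor of the scale on the arrays of other groups.

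In peritoneal macrophages Serpinb2, an inhibitor of plasminogen activators (probe ILMN_1253874), reached 13.44 ± 0.17 (SD, n = 2) and was at least 138-fold higher than in every other group. Selp, the adhesion molecule P-selectin, was at least 125-fold higher and F5, coagulation factor V, at least 124-fold. Prtn3, a serine protease, Ltbp1, a binding protein of latent TGF-beta, and Vmn2r26, a vomeronasal receptor, were at least 67.2-, 58- and 32-fold higher. Gata6, a zinc finger transcription factor, was at 11.86 ± 0.35 (SD, n = 2), at least 46.1-fold higher (adjusted p = 1.49e-05). Tgfb2, a TGF-beta ligand, was 56.5-fold above alveolar macrophages, the next-highest group. The adjusted p of these 8 genes ran from 2.89e-06 to 3.5e-05. Of the peritoneal identity list, not independent evidence, 21 of 21 genes rose, with a median log2 difference of 6.47 (6.10 with undetected levels at their bound; adjusted p = 2.57e-20, and adjusted p = 0.187 with an estimated correlation). Saa3, an acute-phase protein, was at least 246-fold above the mean of the other groups.

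Several functional lists were lower in peritoneal macrophages. Of 25 immediate early genes, which respond within minutes to stimulation and to cell handling, 20 fell and 2 rose (adjusted p = 3.24e-09, and adjusted p = 0.187 with an estimated correlation), including Fos (28.1-fold lower), Jun (22.3-fold) and Fosb (at least 20.3-fold). Of 13 MHC class II and antigen presentation genes 9 fell and 1 rose, among them Ciita, the master activator of class II genes (at least 5.79-fold), and H2-Eb1 (9.76-fold; adjusted p = 0.000389 for the list, and adjusted p = 0.392 with an estimated correlation). Of 23 chemokines 16 fell and 6 rose (adjusted p = 0.00346, and adjusted p = 0.209 with an estimated correlation); Ccl4 was 45-fold lower while Cxcl13, which attracts B cells, was at least 69.5-fold higher. Interferon response genes fell in 15 of 20 cases and 2 rose (adjusted p = 0.00029, and adjusted p = 0.291 with an estimated correlation), with Rsad2 8.52-fold lower. Cholesterol biosynthesis genes fell in 13 of 18 cases and 2 rose (adjusted p = 0.00111, and adjusted p = 0.187 with an estimated correlation), with Cyp51 4.76-fold lower. Of 14 genes of the cultured macrophage list 9 fell and 1 rose (adjusted p = 0.0193, and adjusted p = 0.22 with an estimated correlation); Cadm1 was at least 13.9-fold lower and Arg1, arginase 1, at least 48-fold higher. That call was lost without the BMDM array (adjusted p = 0.144; range over 16 alternatives 0.00409 to 0.144). Adjusted over the list alone, 21 instead of 20 immediate early genes fell and the other counts were the same.

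Lists of 3 other cell types were lower in peritoneal macrophages also when the groups where that list was up were left out of the mean. Endothelial genes fell in 15 of 19 cases and 1 rose (adjusted p = 1.34e-05, and adjusted p = 0.213 with an estimated correlation), with a median of -1.23 and of -0.45 without the groups where the list was up. T and NK cell genes fell in 10 of 12 cases (11 adjusted over the list alone; adjusted p = 5.99e-05, and adjusted p = 0.187 with an estimated correlation), with medians of -1.16 and -0.74. Dendritic cell genes fell in 11 of 15 cases and 2 rose (adjusted p = 0.00154, and adjusted p = 0.225 with an estimated correlation), with medians of -1.28 and -0.997. With undetected levels at their bound the medians against all 6 groups were -0.64, -0.04 and -0.35 in the same order.

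In all, 215 transcripts (156 named genes) were higher in peritoneal macrophages than in every other group. With array set as a block there were 243 (210 shared), and 208 of the 215 were at least 2-fold above every other array within each set. The count was 143 without adipose replicate 2, 143 without background correction and 115 with median scaling.

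Alveolar macrophages were set apart by Krt79, a keratin (probe ILMN_2674304), at 14.17 and at least 236-fold higher than in every other group (adjusted p = 1.24e-05). Scgb1a1, the secretoglobin of airway club cells, was at least 40-fold higher, Gal, the neuropeptide galanin, at least 38.5-fold and Ffar4, a receptor for long-chain fatty acids, at least 37.3-fold. Trim29 and Cxcr1, a chemokine receptor, were at least 28.8- and 16.3-fold higher. Ctsk, the protease cathepsin K, was 48.3-fold above BMDM, and Cd2, an adhesion molecule of lymphocytes, 44.9-fold above splenic macrophages. Of the alveolar identity list, not independent evidence, 13 of 14 genes rose, with a median of 3.82 (3.15 with undetected levels at their bound; adjusted p = 4.91e-12, and adjusted p = 0.187 with an estimated correlation). Cidec, a lipid droplet protein, was at least 44.8-fold and Car4, a carbonic anhydrase, at least 34.6-fold above the mean of the other groups.

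The complement list was lower in alveolar macrophages: 8 of 15 genes fell (10 adjusted over the list alone) and 0 rose (adjusted p = 3.81e-05, and adjusted p = 0.187 with an estimated correlation). C1qb, C1qc and C1qa, which form the C1q recognition molecule, were not detected there and were at least 347-, 331- and 198-fold lower than the mean of the other groups. Of 20 interferon response genes 18 fell and 2 rose (adjusted p = 1.33e-08, and adjusted p = 0.187 with an estimated correlation), with Ifitm3 37.6-fold and Rsad2 at least 18.6-fold lower. Of 22 heme and iron genes 13 fell and 2 rose (adjusted p = 0.00607, and adjusted p = 0.202 with an estimated correlation), with the metal transporter Slc11a1 18.6-fold and the iron exporter Slc40a1 11.8-fold lower. Cell cycle genes rose in 13 of 21 cases and 0 fell (adjusted p = 3.07e-05, and adjusted p = 0.392 with an estimated correlation). Bub1b, a mitotic checkpoint kinase, was at least 3.85-fold higher. With median scaling it missed the threshold, as did Cdk1, Nusap1 and Rrm2. The median of the cell cycle list ran from 0.03 to 1.21 over 16 alternatives, of which 0 lost the call. Cholesterol biosynthesis genes rose in 9 of 18 cases and 0 fell, with Mvd at least 3.84-fold and Sqle at least 3.73-fold higher (adjusted p = 0.00146, and adjusted p = 0.187 with an estimated correlation); with median scaling the list median changed from 0.70 to -0.03, against -0.55 for all transcripts.

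Lists of other cell types also passed on the alveolar array. Of 10 lung epithelial genes 7 rose (8 adjusted over the list alone) and 0 fell (adjusted p = 7.49e-06, and adjusted p = 0.187 with an estimated correlation), including the surfactant proteins Sftpc (at least 12-fold) and Sftpd (at least 10.5-fold). With detection required on at least 2 arrays, which removes genes seen on this array alone, that list no longer passed (adjusted p = 0.0967; range over 16 alternatives 1.8e-10 to 0.0967). Of 12 T and NK cell genes 7 rose (8 adjusted over the list alone) and 2 fell (adjusted p = 0.0084, and adjusted p = 0.202 with an estimated correlation), with Klrd1 at least 6.04-fold higher. In all, 267 transcripts (196 named genes) were higher in alveolar macrophages than in every other group, 309 with array set as a block (247 shared). Of the 267, 263 were at least 2-fold above every other array of the dimmer set, a share that the counting rule nearly fixes. The count was 145 with detection on at least 2 arrays and 73 with median scaling.

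Kupffer cells were led by Clec4f, a lectin of these cells (probe ILMN_2702159), at 14.81 and at least 356-fold higher than in every other group (adjusted p = 1.3e-05). The other 7 leading genes are products for which the liver is known. Mat1a, a methionine adenosyltransferase, was at least 44.3-fold higher, the apolipoprotein Apoa2 at least 39-fold and the kininogen Kng1 at least 29-fold. Serpina1b, Serpina1e and Serpina1d, which encode alpha-1-antitrypsins, were at least 35.3-, 34.1- and 22.6-fold higher, and Mup3, a major urinary protein, at least 16.4-fold. Of 14 hepatocyte genes 13 rose, with a median of 4.42 (3.35 with undetected levels at their bound; adjusted p = 2.12e-14, and adjusted p = 0.187 with an estimated correlation), and Ttr, the thyroid hormone carrier, was at least 11.9-fold higher. Of 19 endothelial genes 14 rose (15 adjusted over the list alone) and 1 fell (adjusted p = 1.63e-10, and adjusted p = 0.187 with an estimated correlation), led by Clec4g (at least 59.8-fold) and Cdh5 (at least 56.1-fold). Cdh5 also stands in the Kupffer identity list, where 19 of 19 genes rose, not independent evidence, with a median of 4.62 (4.26 with undetected levels at their bound; adjusted p = 4.97e-21, and adjusted p = 0.187 with an estimated correlation). Vsig4, a complement receptor, was at least 81.2-fold and Cd207, the lectin langerin, at least 46.4-fold above the mean of the other groups.

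Several functional lists passed in Kupffer cells. Complement genes rose in 12 of 15 cases (adjusted p = 3e-08, and adjusted p = 0.187 with an estimated correlation), with C6 at least 23.7-fold and Fcna, a ficolin, at least 16.3-fold higher. Scavenger and phagocytic receptors rose in 15 of 20 cases and 3 fell (adjusted p = 2.55e-05, and adjusted p = 0.187 with an estimated correlation), with Stab2, a hyaluronan receptor, at least 37.3-fold higher. Heme and iron genes rose in 11 of 22 cases and 2 fell (adjusted p = 0.00122, and adjusted p = 0.187 with an estimated correlation), with the heme carrier Hpx at least 15.2-fold and Slc40a1 at least 13.2-fold higher. Hpx also stands in the hepatocyte list and Stab2 in the endothelial list, both of which were up on this array. Interferon response genes rose in 10 of 20 cases (adjusted p = 2.22e-06, and adjusted p = 0.209 with an estimated correlation), with Irf7 at least 7.13-fold higher. Lineage regulators rose in 11 of 29 cases and 4 fell (adjusted p = 0.00873, and adjusted p = 0.26 with an estimated correlation), with Id3 19.1-fold and Nr1h3 13.8-fold higher, although with median scaling the list median was -0.04, against -0.41 for all transcripts. Cell cycle genes fell in 15 of 21 cases (adjusted p = 9.2e-05, and adjusted p = 0.417 with an estimated correlation), with the replication factor Mcm6 3.35-fold lower. Cholesterol biosynthesis genes fell in 11 of 18 cases (adjusted p = 4.42e-05, and adjusted p = 0.187 with an estimated correlation), with Sqle at least 3.43-fold lower. Adjusted over the list alone, 13 complement genes rose and 2 fell, 16 scavenger receptors and 11 interferon genes rose, 3 heme and iron genes fell, 13 regulators rose and 5 fell, 1 cell cycle gene rose and 16 fell, and 13 cholesterol genes fell.

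For a pair of further lists the call in Kupffer cells depended on the setting. MHC class II genes rose in 9 of 13 cases (10 adjusted over the list alone) and 2 fell (adjusted p = 0.00255, and adjusted p = 0.455 with an estimated correlation), with H2-Ab1 3.42-fold higher. Without the BMDM array that list no longer passed (adjusted p = 0.0871; range over 16 alternatives 2.08e-05 to 0.0871). Toll-like receptor and inflammasome genes rose in 8 of 21 cases and 2 fell (adjusted p = 0.0409, and adjusted p = 0.413 with an estimated correlation), with the cytokines Il1b and Il1a at least 16.1- and 10.1-fold higher. This call was lost under 4 of 16 alternatives (range 0.00314 to 0.0878), among them array set as a block (adjusted p = 0.0505), the fit without the BMDM array (adjusted p = 0.0711) and median scaling, where the median turned to -0.22 (adjusted p = 0.0878). In all, 141 transcripts (118 named genes) were higher in Kupffer cells than in every other group, 162 with array set as a block (129 shared). Of the 141, 141 were at least 2-fold above every other array of the dimmer set, a share that the counting rule nearly fixes. The count was 84 without adipose replicate 1, 84 without adipose replicate 2, 93 with the authors' values, 79 without background correction, 47 with median scaling and 36 with detection on at least 2 arrays.

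Splenic red pulp macrophages, which clear aged red blood cells, had Hs3st2, a heparan sulfate sulfotransferase (probe ILMN_2517786), at 12.65, at least 79.4-fold higher than in every other group (adjusted p = 2.38e-05). Slc4a1, the band 3 anion exchanger of red blood cells, was at least 90-fold higher, Sned1 at least 49.1-fold and Vstm4 at least 44.5-fold. Ubd, a ubiquitin-like protein, was at least 25-fold, Lrrn3 at least 14.6-fold and the chemokine receptor Ccr3 at least 9.61-fold higher. Itgad, the integrin chain CD11d, was 66.7-fold above alveolar macrophages, the next-highest group. Of the splenic identity list, not independent evidence, 13 of 15 genes rose and 1 fell, with a median of 4.07 (3.49 with undetected levels at their bound; adjusted p = 3.28e-09, and adjusted p = 0.187 with an estimated correlation). In Kupffer cells 11 of those 15 genes also rose and 1 fell (adjusted p = 4.48e-06, and adjusted p = 0.187 with an estimated correlation). Heme and iron genes rose in 10 of 22 cases (12 adjusted over the list alone) and 3 fell (5 adjusted over the list alone; adjusted p = 0.00794, and adjusted p = 0.202 with an estimated correlation). Among them Spic was at least 45.4-fold, Slc40a1 at least 14.6-fold and Hmox1, the heme-degrading oxygenase, 4.4-fold higher, and Hp, haptoglobin, was at least 7.15-fold lower.

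Lists of 3 other cell types were higher on the splenic array. Of 10 erythroid genes 8 rose (adjusted p = 3.85e-06, and adjusted p = 0.187 with an estimated correlation), with Alas2, which starts erythroid heme synthesis, at least 47.2-fold and the globin Hba-a1 at least 36.9-fold higher. Of 8 B cell genes 6 rose and 1 fell (adjusted p = 0.00143, and adjusted p = 0.342 with an estimated correlation), with Cd79b 11.6-fold and Cd79a at least 5.1-fold higher. Of 12 T and NK cell genes 7 rose and 1 fell (adjusted p = 0.0473, and adjusted p = 0.274 with an estimated correlation), with Cd3d at least 3.26-fold higher. That last call was lost under 9 of 16 alternatives (range 0.0145 to 0.267), including array set as a block (adjusted p = 0.0822) and the fits without peritoneal replicate 1 (0.0584), peritoneal replicate 2 (0.0648) or adipose replicate 2 (0.0566).

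Among the lists lower in splenic macrophages, chemokines fell in 18 of 23 cases and 1 rose, with a median of -2.29 (-1.80 with undetected levels at their bound; adjusted p = 3.93e-09, and adjusted p = 0.187 with an estimated correlation). Ccl9 was 37.7-fold and Ccl3 at least 28.6-fold lower. Alternative activation genes fell in 11 of 17 cases (12 adjusted over the list alone) and 2 rose (adjusted p = 0.000912, and adjusted p = 0.187 with an estimated correlation), with the lectin Mgl2 at least 16.5-fold lower. Genes of the cultured macrophage list fell in 11 of 14 cases and 2 rose (adjusted p = 0.000376, and adjusted p = 0.187 with an estimated correlation), with Gpnmb at least 31-fold and Trem2 at least 17.8-fold lower. Coagulation genes fell in 14 of 17 cases and 1 rose (adjusted p = 7.46e-05, and adjusted p = 0.187 with an estimated correlation); the anticoagulant Pros1 was 12.2-fold and the urokinase receptor Plaur 8.14-fold lower, while the list median moved from -1.36 to 0.00 with undetected levels at their bound.

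A further 3 splenic lists passed but lost their call without the BMDM array. Cholesterol biosynthesis genes fell in 10 of 18 cases (adjusted p = 0.00192, and adjusted p = 0.187 with an estimated correlation; 0.0747 without that array, range over 16 alternatives 9.21e-06 to 0.0747), with Cyp51 2.09-fold lower. Cell cycle genes fell in 8 of 21 cases (adjusted p = 0.0106, and adjusted p = 0.546 with an estimated correlation; 0.276 without that array, range 0.000243 to 0.276), with Bub1b at least 2.34-fold lower. Of 13 MHC class II and antigen presentation genes 7 rose and 1 fell (adjusted p = 0.0457, and adjusted p = 0.548 with an estimated correlation). Of its costimulatory genes, Cd86 was 5.14-fold higher and Cd40 at least 7.91-fold lower. The class II pathway genes Cd74 and H2-Oa also rose, but missed the threshold with median scaling. The last list failed under 9 of 16 alternatives (range 0.00228 to 0.721), among them array set as a block (0.222) and the fits without small intestinal replicate 2 (0.052) or the BMDM array (0.721). In all, 245 transcripts (156 named genes) were higher in splenic macrophages than in every other group, 305 with array set as a block (219 shared). Of the 245, 244 were at least 2-fold above every other array of the dimmer set, a share that the counting rule nearly fixes. The count was 141 and 140 without small intestinal replicates 1 and 2, and 123 and 122 without adipose replicates 1 and 2. It was 163 with the authors' values, 152 without background correction, 119 with detection on at least 2 arrays and 55 with median scaling.

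In small intestinal macrophages Il1r2, a decoy receptor for interleukin 1 (probe ILMN_2611000), was at 10.19 ± 0.12 (SD, n = 2) and at least 14.5-fold higher than in every other group (adjusted p = 4.59e-05). Klra17, a lectin-like receptor, and Apol10b were at least 23.2- and 23.4-fold higher. Actg2, the actin of gut smooth muscle, was at least 16.2-fold higher, and Defa3 and Defa20, alpha-defensins of Paneth cells, at least 12.2- and 11.6-fold. Mmp2, a gelatinase, was 26-fold above adipose macrophages and Ocstamp, a cell fusion protein, 25.3-fold above splenic macrophages. Of the intestinal identity list, not independent evidence, 19 of 19 genes rose, with a median of 3.13 (2.91 with undetected levels at their bound; adjusted p = 1.35e-12, and adjusted p = 0.187 with an estimated correlation), including the collagenase Mmp13 (at least 48-fold) and the chemokine receptor Cx3cr1 (at least 39.4-fold). Of the adipose identity list 10 of 19 genes also rose (11 adjusted over the list alone) and 4 fell (adjusted p = 0.0315, and adjusted p = 0.249 with an estimated correlation).

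Antigen presentation, chemokine and immediate early genes were higher in intestinal macrophages. Of 13 MHC class II genes 12 rose, with a median of 2.15 (2.15 with undetected levels at their bound; adjusted p = 1.48e-06, and adjusted p = 0.291 with an estimated correlation). Ciita was at least 14.7-fold and H2-Eb1 11.9-fold higher. Chemokines rose in 18 of 23 cases and 2 fell (adjusted p = 9.38e-07, and adjusted p = 0.187 with an estimated correlation), with the monocyte attractant Ccl12 at least 37.6-fold and Cxcl9 at least 26.3-fold higher. Immediate early genes rose in 24 of 25 cases, with a median of 1.65 (1.55 with undetected levels at their bound; adjusted p = 1.1e-10, and adjusted p = 0.187 with an estimated correlation), with the stress phosphatase subunit Ppp1r15a 9.08-fold and Atf3 8.88-fold higher. Alternative activation genes rose in 13 of 17 cases (14 adjusted over the list alone) and 2 fell (adjusted p = 0.00036, and adjusted p = 0.187 with an estimated correlation), with Mgl2 at least 5.73-fold and Retnla at least 4.12-fold higher. Lipid genes fell in 13 of 23 cases and 4 rose (adjusted p = 0.00809, and adjusted p = 0.213 with an estimated correlation); Lpl, lipoprotein lipase, was 14.8-fold lower and Dgat2, of triglyceride synthesis, at least 7.38-fold higher.

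Lists of 3 other cell types were higher in intestinal macrophages as well. Dendritic cell genes rose in 12 of 15 cases and 1 fell (adjusted p = 5.99e-05, and adjusted p = 0.187 with an estimated correlation), with the integrin chain Itgae at least 34.2-fold and Dpp4 at least 16.7-fold higher. Epithelial and Paneth cell genes rose in 12 of 15 cases and 2 fell (adjusted p = 0.000253, and adjusted p = 0.279 with an estimated correlation), with Rbp2, a retinol-binding protein of enterocytes, at least 3.27-fold higher. Fibroblast and mesothelial genes rose in 10 of 16 cases (11 adjusted over the list alone) and 1 fell (adjusted p = 0.000297, and adjusted p = 0.202 with an estimated correlation), with Acta2, smooth muscle actin, at least 13.5-fold higher. Adipocyte genes fell in 7 of 10 cases and 1 rose, with a median of -0.53 (-0.20 with undetected levels at their bound; adjusted p = 0.0103, and adjusted p = 0.209 with an estimated correlation).

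A further 3 intestinal lists passed with calls that depended on the setting. Receptors for chemokines and cytokines rose in 10 of 23 cases and 4 fell (adjusted p = 0.0181, and adjusted p = 0.342 with an estimated correlation), with Ccr7 at least 5.28-fold higher; this call was lost with array set as a block (0.118) and under 3 of 16 alternatives (range 0.000963 to 0.141). Cell cycle genes fell in 8 of 21 cases (adjusted p = 0.016, and adjusted p = 0.548 with an estimated correlation), but their median of -0.53 turned to 0.06 with array set as a block (adjusted p = 0.705) and to 0.04 with median scaling (0.082). Without the BMDM array the adjusted p was 0.529 (range over 16 alternatives 0.00366 to 0.705), and Cdk1, 2.26-fold lower, missed the threshold with median scaling. Heme and iron genes fell in 11 of 22 cases (12 adjusted over the list alone) and 3 rose (4 adjusted over the list alone; adjusted p = 0.0331, and adjusted p = 0.249 with an estimated correlation), with Lrp1 5.13-fold lower, but with median scaling their median turned from -0.48 to 0.17, against 0.58 for all transcripts. Without peritoneal replicate 2 the adjusted p of that list was 0.0501 (range over 16 alternatives 0.00851 to 0.0501). In all, 309 transcripts (169 named genes) were higher in intestinal macrophages than in every other group, 293 with array set as a block (266 shared), and 299 of the 309 were at least 2-fold above every other array of the brighter set. The count was 168 with the authors' values and 140 without background correction.

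In adipose tissue macrophages Cd209d, a DC-SIGN family lectin (probe ILMN_2696291), was at 10.51 ± 0.01 (SD, n = 2) and at least 18.1-fold higher than in every other group (adjusted p = 3.1e-05), and its relative Cd209g was at least 11.1-fold higher. Egfr, the epidermal growth factor receptor, was at least 14.6-fold, Car3, a carbonic anhydrase abundant in fat cells, at least 8.34-fold, Prm1, a sperm protamine, at least 7.97-fold and the ribonuclease Rnase2a at least 6.84-fold higher. Fxyd2, a regulator of the sodium pump, was 21.5-fold above intestinal and Rcn3 15.2-fold above splenic macrophages. Of the adipose identity list, not independent evidence, 19 of 19 genes rose, with a median of 4.68 (3.69 with undetected levels at their bound; adjusted p = 1.29e-16, and adjusted p = 0.187 with an estimated correlation). Retnla, a marker of alternative activation, was at least 120-fold, Mgl2 at least 67.8-fold, Ccl8 at least 35.1-fold and Lyve1, a hyaluronan receptor, at least 33.4-fold above the mean of the other groups.

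Immediate early genes rose in 21 of 25 cases and 1 fell (2 adjusted over the list alone), with a median of 1.05 (1.05 with undetected levels at their bound; adjusted p = 9.38e-07, and adjusted p = 0.187 with an estimated correlation), with Egr1 4.76-fold and Atf3 4.09-fold higher. Fibroblast and mesothelial genes rose in 11 of 16 cases (12 adjusted over the list alone) and 1 fell (2 adjusted over the list alone; adjusted p = 3.9e-05, and adjusted p = 0.187 with an estimated correlation), with the proteoglycan Dcn at least 20.9-fold higher. Cell cycle genes fell in 15 of 21 cases (16 adjusted over the list alone) and 1 rose (adjusted p = 2.03e-05, and adjusted p = 0.392 with an estimated correlation), with Tk1, thymidine kinase, 6.71-fold lower. T and NK cell genes fell in 9 of 12 cases (10 adjusted over the list alone; adjusted p = 0.000297, and adjusted p = 0.187 with an estimated correlation), with a median of -0.97 (-0.22 with undetected levels at their bound) and of -0.44 without the alveolar and splenic groups in the mean. The adipocyte list did not pass (adjusted p = 0.242), with 4 of 10 genes higher (5 adjusted over the list alone), 3 lower and a median of 0.33. Adipoq, the adipocyte hormone adiponectin, was nevertheless at 9.03 and at least 7.26-fold above the mean of the other groups, and Car3 at least 9.33-fold.

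The other 5 adipose lists passed with calls that depended on the setting. Chemokines rose in 13 of 23 cases (14 adjusted over the list alone) and 5 fell (6 adjusted over the list alone; adjusted p = 0.00573, and adjusted p = 0.22 with an estimated correlation), with Cxcl12 at least 19.3-fold higher, and the call was lost with median scaling (0.204; range over 16 alternatives 3.78e-05 to 0.204). Cholesterol biosynthesis genes fell in 10 of 18 cases (13 adjusted over the list alone; adjusted p = 0.00111, and adjusted p = 0.187 with an estimated correlation), with Sqle 2.89-fold lower, but with median scaling their median turned from -0.63 to 0.14, against 0.72 for all transcripts. Without the BMDM array that list no longer passed (0.0861; range over 16 alternatives 1.2e-05 to 0.0861). MHC class II genes rose in 8 of 13 cases (9 adjusted over the list alone) and 4 fell (adjusted p = 0.0427, and adjusted p = 0.546 with an estimated correlation), with H2-Eb1 6.71-fold higher; this call was lost under 4 of 16 alternatives (range 0.0014 to 0.304), the highest without the BMDM array. Complement genes rose in 8 of 15 cases and 3 fell (adjusted p = 0.0261, and adjusted p = 0.318 with an estimated correlation), with Fcna at least 14.6-fold higher; the call was lost under 4 of 16 alternatives (range 0.00488 to 0.167), including the fit without the BMDM array (0.0861). Endothelial genes rose in 10 of 19 cases (11 adjusted over the list alone) and 3 fell (4 adjusted over the list alone; adjusted p = 0.0264, and adjusted p = 0.417 with an estimated correlation), with Cldn5 at least 4.74-fold higher. Their median of 0.61 was 0.00 with undetected levels at their bound, and the call was lost under 4 of 16 alternatives (range 0.00016 to 0.865), including the fit without the BMDM array (0.261).

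In all, 131 transcripts (105 named genes) were higher in adipose macrophages than in every other group, 135 with array set as a block (107 shared), and 124 of the 131 were at least 2-fold above every other array of the brighter set. The count was 71 and 69 without small intestinal replicates 1 and 2, 46 and 42 without adipose replicates 1 and 2, 86 with the authors' values and 74 without background correction.

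Before BMDM were compared with the tissues, sex-linked transcripts were read as a check of the labels. Xist, the RNA of the inactive X chromosome found in female cells, was at 9.69 on the BMDM array by 1 of its 2 probes, and at 4.85 to 5.51, not detected, on all 9 tissue arrays. Eif2s3y, encoded on the Y chromosome, was at 4.80 and not detected on the BMDM array, against 7.75 to 8.70 on the tissue arrays. Kdm5d, also on the Y chromosome, was at 4.56 on the BMDM array and at 4.89 to 6.36 on the tissue arrays. The Y-linked Uty went the other way: its brightest probe was at 6.18 on the BMDM array, within the tissue range of 5.38 to 6.34, and it was narrowly detected there and on 3 of 9 tissue arrays. Of X-linked genes that were also read, Eif2s3x was 1.32 above the mean of the tissue groups on the BMDM array, while Ddx3x was at -0.77 and the 2 bright Kdm6a probes at -0.42 and -0.57 relative to it. By Xist and Eif2s3y the array labelled male BMDM thus went against its sex label, and each direction given for BMDM carries this difference. Of the named genes higher in BMDM than in every other group, 9 of 277 (3.25%) lie on the X chromosome, against 254 of 9166 (2.77%) of those tested (Fisher's exact test, two-sided p = 0.576). That share cannot exclude a contribution of sex, which need not act through X-linked genes.

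**Figure D3:**
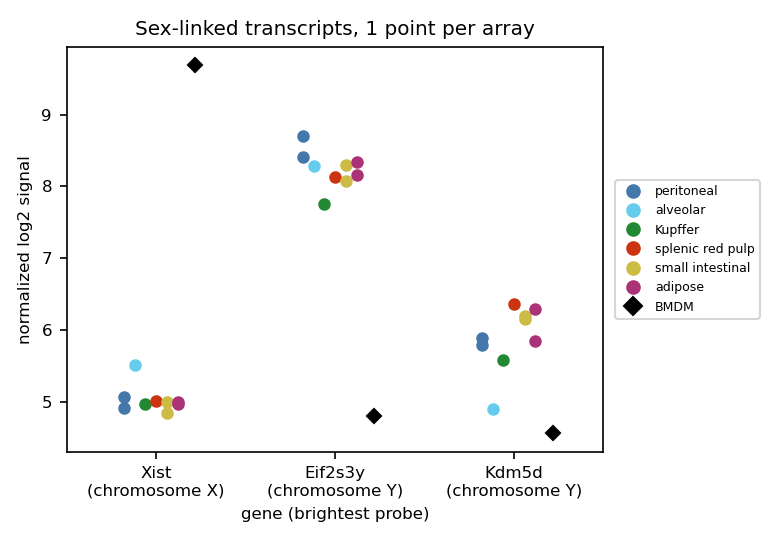
Normalized log2 signal of 3 sex-linked genes (horizontal axis, brightest probe of each) with 1 point per array, coloured by group, and the BMDM array as a black diamond. The BMDM array lies at 9.69 for Xist, above all tissue arrays (4.85 to 5.51), and at 4.80 for Eif2s3y, below all of them (7.75 to 8.70).

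The comparison of the array labelled BMDM with the mean of the 6 tissue groups asked how cultured and tissue macrophages differ. The neuropeptide Npy (probe ILMN_1243928) was at 13.08 in BMDM and at least 125-fold above the tissue mean (adjusted p = 9.41e-06). The monocyte attractants Ccl7 and Ccl2 were at least 61.5- and 34.7-fold higher, and Acod1, which makes itaconate, at least 54.7-fold. Kcnn4, a potassium channel, Gpr84, a receptor for medium-chain fatty acids, and Gpnmb, a lysosomal glycoprotein, were at least 44.9-, 44.4- and 41.3-fold higher. Adam8, the creatine transporter Slc6a8, the interleukin 7 receptor chain Il7r, Pdpn and the phosphatase Dusp4 were higher by at least 38.6-, 35.5-, 35.4-, 32.1- and 24.4-fold. In the other direction, the globins Hbb-bt, Hbb-bs and Hba-a1 were at least 64.7-, 60.1- and 47.8-fold lower in BMDM, and Ear3, a ribonuclease, at least 61-fold. The globins were also below the lowest detected level on peritoneal replicate 2, with Hba-a1 at 4.77 there against 4.75 in BMDM. Sult1a1, a sulfotransferase, and Apoc1, an apolipoprotein, were at least 55.5- and 21.9-fold lower. The class II genes H2-Eb1, H2-Ab1 and H2-Aa were 39-, 35.1- and 29.2-fold lower. Ms4a8a, Timd4, a receptor for dying cells, and Vsig4 were at least 14.6-, 12.8- and 12.6-fold lower.

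Genes of proliferation, sterol synthesis and interferon response were higher in BMDM. Cell cycle genes rose in 19 of 21 cases (20 adjusted over the list alone), with a median of 2.04 (1.87 with undetected levels at their bound; adjusted p = 7.77e-09, and adjusted p = 0.291 with an estimated correlation), with Mcm6 8.62-fold and Cdk1 at least 7.91-fold higher. Cholesterol biosynthesis genes rose in 16 of 18 cases (17 adjusted over the list alone; adjusted p = 1.42e-08, and adjusted p = 0.187 with an estimated correlation), with Sqle, squalene epoxidase, at least 24.1-fold and Fdps 10.3-fold higher. Interferon response genes rose in 18 of 20 cases and 1 fell (adjusted p = 1.07e-08, and adjusted p = 0.187 with an estimated correlation), with Ifit2 at least 11.3-fold and Oas3 at least 9.14-fold higher. Genes of the cultured macrophage list rose in 12 of 14 cases and 2 fell (adjusted p = 7.71e-05, and adjusted p = 0.187 with an estimated correlation), with the aminopeptidase Anpep at least 20.5-fold and Mmp12 at least 10.4-fold higher. MHC class II genes fell in 11 of 13 cases and 1 rose, with a median of -3.10 (-2.69 with undetected levels at their bound; adjusted p = 2.03e-05, and adjusted p = 0.341 with an estimated correlation), with Cd74, the invariant chain, 25.9-fold lower. Alternative activation genes fell in 15 of 17 cases (16 adjusted over the list alone; adjusted p = 2.03e-05, and adjusted p = 0.187 with an estimated correlation), with Ccl24 at least 18-fold and Retnla at least 7-fold lower. Immediate early genes fell in 19 of 25 cases (adjusted p = 1.34e-05, and adjusted p = 0.187 with an estimated correlation), with Egr1 9.46-fold and Klf2 6.78-fold lower.

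Lists of 2 other cell types were lower on the BMDM array also when the groups where that list was up were left out of the mean. Dendritic cell genes, whose list has no gene of the class II list, fell in 13 of 15 cases and 1 rose (adjusted p = 0.000311, and adjusted p = 0.202 with an estimated correlation), with a median of -1.81 and of -1.43 without the intestine. Endothelial genes fell in 15 of 19 cases (adjusted p = 8.26e-05, and adjusted p = 0.246 with an estimated correlation), with a median of -1.54 and of -0.90 without Kupffer cells and adipose tissue. With undetected levels at their bound the medians against all 6 groups were -0.56 and -0.74.

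In this comparison 6721 transcripts differed, of which 2919 were higher and 3802 lower in BMDM; of these, 1422 were at least 2-fold higher than the tissue mean and above all 9 tissue arrays, and 1475 were at least 2-fold lower and below all 9. With array set as a block the number was 8113 (6636 shared), with a minimum of 2-fold 3883 and with median scaling 3647 (1226 higher and 2421 lower). Against every other group, 378 transcripts (277 named genes) were higher in BMDM, led by Npy (adjusted p = 0.000173), Il7r (24.9-fold over the intestine), Gpr84 (24.7-fold over Kupffer cells), Kcnn4 (23.1-fold over the spleen) and Dusp4 (at least 21.1-fold). Tmem171, the serotonin receptor Htr2b and the transcription factor Zic4 were at least 14-, 11.1- and 9.06-fold higher. With array set as a block 501 transcripts were counted (356 shared). Of the 378, 371 were at least 2-fold above every other array of the dimmer set, a share that the counting rule nearly fixes. The count was 207 and 204 without small intestinal replicates 1 and 2, 182 without adipose replicate 1 and 182 without adipose replicate 2. It was 243 with the authors' values, 201 without background correction, 227 with detection on at least 2 arrays and 83 with median scaling.

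The last comparisons set each tissue against the array labelled BMDM. Chemokines were lower than in BMDM in the spleen (14 of 23 lower and 4 higher, median -2.61, adjusted p = 0.000307, and adjusted p = 0.216 with an estimated correlation) and in the peritoneum (12 lower and 5 higher, median -0.72, adjusted p = 0.013, and adjusted p = 0.304 with an estimated correlation). In intestinal macrophages they were higher (15 higher and 4 lower, median 1.08, adjusted p = 0.0315, and adjusted p = 0.308 with an estimated correlation). Splenic macrophages differed from BMDM in 6136 transcripts (3196 higher and 2940 lower than in BMDM), Kupffer cells in 5501 (2857 and 2644), and peritoneal macrophages in 5383 (2853 and 2530). Alveolar macrophages differed in 4668 (2450 and 2218). Intestinal macrophages differed in 6824 (3838 and 2986) and adipose macrophages in 5949 (3356 and 2593), but both arrays of those groups lay in the brighter set and the BMDM array in the dimmer one. With array set as a block the numbers were 7907 for the spleen, 7451 for Kupffer cells, 6906 for the peritoneum, 6745 for the lung, 6613 for the intestine and 6031 for adipose tissue, with 6136, 5501, 5318, 4668, 5363 and 4656 shared in that order. For the spleen, Kupffer cells and lung these equal the numbers without a peritoneal array. Both fits take the spread from the intestinal and adipose pairs, which lay closer together than the peritoneal pair. The larger numbers and full overlap are therefore not evidence against an effect of the set. Within the dimmer set alone the groups have 1 array each, so no test is left there. With median scaling the numbers were 3151 for the spleen (1686 higher and 1465 lower), 2460 for Kupffer cells (1159 and 1301), 2793 for the peritoneum (1757 and 1036) and 2033 for the lung (828 and 1205). For the intestine the split moved from 56.2% higher to 82.9% (4582 higher and 947 lower of 5529), and for adipose tissue from 56.4% to 86.2% (4729 and 756 of 5485).

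**Figure D4:**
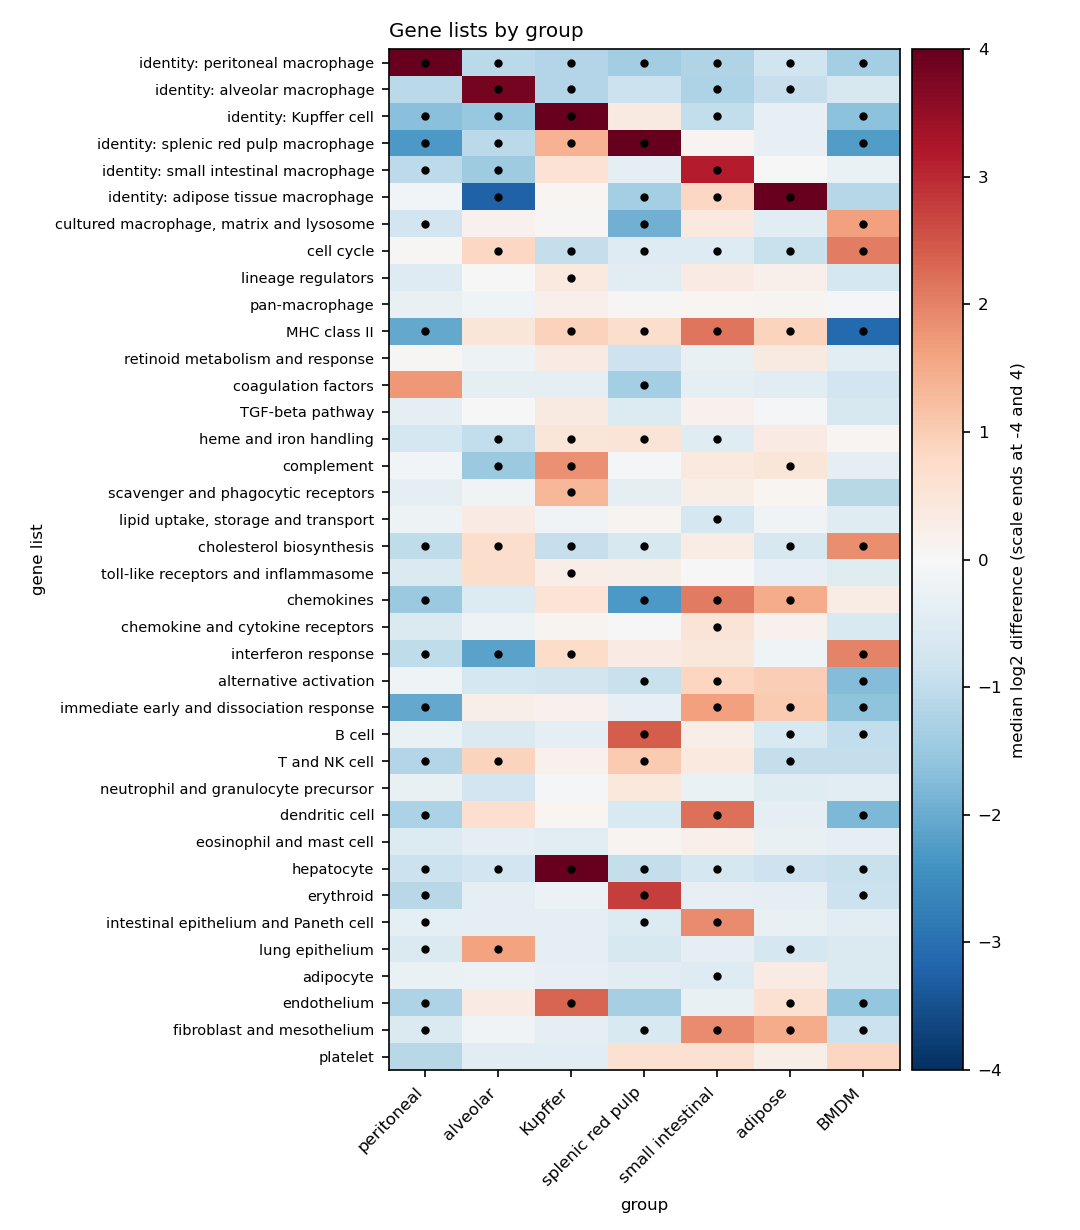
Median log2 difference of each of the 38 gene lists (vertical axis) between a group (horizontal axis) and the mean of the other 6 groups, on a colour scale that ends at -4 and 4. A black dot marks the 113 of 266 tests that passed with the preset correlation; 0 of them passed with an estimated correlation.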

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

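The gene list tests of each group against the mean of the others were planned; the direct comparisons of chemokines and the tests of explanations in this part were chosen only after the results were seen.

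Chemokine genes differed between tissues when each was set against the BMDM array. Of the 23 genes, 15 were higher and 4 lower than in BMDM in small intestinal macrophages, while 12 were lower and 5 higher in peritoneal and 14 lower and 4 higher in splenic macrophages. Compared directly, the median log2 difference between the intestine and the peritoneum was 3.13 (camera, adjusted p = 0.000518 over 285 tests with the preset correlation, and 0.301 with an estimated one). Between the intestine and the spleen it was 3.78 (adjusted p = 1.35e-11, and 0.301 with an estimated correlation). Both intestinal arrays and the splenic array lay in different array sets, and the direct comparisons were not repeated with array set as a block. Against the mean of the other groups, the list kept its call with that block in the intestine, spleen and peritoneum. The block rests on the peritoneal pair alone. No other explanation of the difference was tested.

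The signal of Xist on the BMDM array, 9.69, went against the male sex in its label. The tables argue against a false signal of the Xist probe alone, since the Y-linked Eif2s3y, not detected in BMDM, lay at -2.07 or lower relative to the mean of the 9 tissue arrays with its level at the floor of that array (fitted -3.43; SD between the tissue arrays 0.261), and against a swap with a tissue array, since the highest median among the 6 tissue identity lists in BMDM was -0.265. A candidate explanation is that the RNA came from female mice: Eif2s3y lay at -1.58 or lower relative to the lowest tissue array by the same bound (fitted -2.95). The Y-linked Uty goes the other way, at 6.18 and narrowly detected, but close to the lowest level of any detected probe on that array (6.17), and of the X-linked genes Eif2s3x was higher than the tissue mean (1.32) and Ddx3x lower (-0.77). Whether the label or the animals differ remains open, and the comparisons with BMDM may therefore include a difference of sex.

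Of the neighbouring-cell lists, for lung epithelium, hepatocytes, erythroid cells, gut epithelium and adipocytes, 4 of 5 were up in their own tissue, and 0 of 30 other list and group pairs were (camera with the preset correlation). A list high in 1 tissue raises the mean that the other groups are set against, so the 0 of 30 partly follows from the test. The erythroid gene Hba-a1 was also high in Kupffer cells (13.98) and the lung (12.24), but not on peritoneal replicate 2 (4.77) or in BMDM (4.75). With an estimated correlation the adjusted p was 0.187 for 3 of the 4 and 0.279 for gut epithelium, so none held, and the lung list also failed with detection on at least 2 arrays (0.0967; range 1.8e-10 to 0.0967). With the array set as a block the largest adjusted p of the 4 lists was 0.000341 (camera, preset correlation). The block rests on the peritoneal pair, so it cannot remove a set effect from genes at the floor on those arrays. It therefore does not exclude the array set. Each of the 4 lists was called up in its own tissue and not in the other groups of the same set. RNA carried over from other cells is a candidate explanation for the 40 of 49 members that were higher in their own tissue, but expression by the macrophages cannot be told apart from it, because the labels name no sort or gate and the albumin probe, the 1 for the most abundant hepatocyte transcript, was detected on 0 of 10 arrays. The 49 are the members detected on at least 1 array: 14 of 22 hepatocyte, 10 of 18 lung, 15 of 25 gut and 10 of 15 erythroid genes on the array. Detection in the own tissue alone was enough, which favours a high share. Other lists also hold 4 of the 14 hepatocyte, 4 of the 10 lung, 7 of the 15 gut and 1 of the 10 erythroid genes.

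Immediate early genes were high on the intestinal and adipose arrays and low on the peritoneal ones. Only the peritoneal pair spans the array sets. Between these arrays, brighter minus dimmer, the members' median difference was 0.125 with quartiles of -0.184 and 0.371 (interquartile range 0.555). The list median was -1.70 against -1.52, so no direction is given. The 0.125 lies far from the gap of 1.83 between the intestinal and adipose arrays and the dimmer set. The list was lowest in the peritoneal group, so this pair cannot exclude a set effect on arrays where these genes were higher. Within the brighter set the list median was -1.70 on the peritoneal array and 1.40 and 1.42 on the intestinal arrays. The array set alone cannot give that difference. The way cells were released from each tissue is a candidate explanation that cannot be told apart from the tissue itself, because 0 lines of the 10 labels name it. A difference between the tissues stays open as well and was not tested.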

How the results depend on the processing

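The array-set block, the fit without the BMDM array and the reduced mean for falling other-cell lists (6 of 23 kept) were chosen after the data were seen; all other alternatives were set before the data were examined. None of the 91 list results followed and of the named genes' results changed direction in its test, but with median scaling the medians of 4 lists that still passed turned sign: cholesterol synthesis in the lung (0.70 to -0.03) and adipose tissue (-0.63 to 0.14), regulators in Kupffer cells (0.38 to -0.04) and heme and iron in the intestine (-0.48 to 0.17). The medians of 2 lists that lost their call turned as well. Over the 16 counts, 221 of 263 values under an alternative lay within 1.5 times the reported count. Of the 91 list results followed, 63 kept their call under every alternative other than the estimated correlation and 28 lost it under at least 1. Of 5340 values for named genes 51 missed the threshold, 20 of them with median scaling. With detection on at least 2 arrays, only 300 of the 340 named-gene results had a value. The others belong to genes that this filter removed, and they are not counted among the 51.

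The numbers of transcripts higher in a group than in every other moved most often. With the authors' values they were 93 in Kupffer cells, 163 in the spleen, 168 in the intestine, 86 in adipose tissue and 243 in BMDM. Without background correction they were 143 in the peritoneum, 79 in Kupffer cells, 152 in the spleen, 140 in the intestine, 74 in adipose tissue and 201 in BMDM. With median scaling they were 115 in the peritoneum, 73 in the lung, 47 in Kupffer cells, 55 in the spleen and 83 in BMDM, and the numbers that differed from BMDM were 2793, 2033, 2460 and 3151 in the peritoneum, lung, liver and spleen, with 3647 for BMDM against the tissue mean. For these 3 settings the cause was not tested. With median scaling the median difference of all transcripts from the mean of the other groups was 0.02 (peritoneum), -0.55 (lung), -0.41 (liver), -0.28 (spleen), 0.58 (intestine), 0.72 (adipose tissue) and -0.26 (BMDM). In the main fit it lay between -0.12 (BMDM) and 0.01 (adipose tissue). Median scaling also turned the share of transcripts higher than in BMDM from 56.2% to 82.9% in the intestine, 56.4% to 86.2% in adipose tissue, 52.5% to 40.7% in the lung and 53% to 62.9% in the peritoneum. Detection on at least 2 arrays removes genes seen on a lone array, which left 145 in the lung, 36 in Kupffer cells, 119 in the spleen and 227 in BMDM. A 2-fold minimum left 3883 for BMDM against the tissues. The estimated correlation left 0 of 113 list calls in camera (63 of 266 at an unadjusted p under 0.05). It also rests the test on the 3 residual degrees of freedom, so the loss cannot be put down to correlation between genes alone.

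Leaving out each array of the 3 replicated groups in turn, or the BMDM array where the result allows (the alveolar, Kupffer and splenic arrays were not left out), the F test gave 8387 to 12031. The numbers higher in a group were 143 to 287 (peritoneum), 192 to 387 (lung), 84 to 184 (liver), 122 to 336 (spleen), 208 to 338 (intestine), 42 to 173 (adipose tissue) and 182 to 480 (BMDM). Against BMDM they were 4434 to 7008, 3644 to 6745, 4469 to 7451, 5211 to 7907, 4890 to 8592 and 3967 to 7956 in the same order of tissues, 5627 to 8642 for BMDM against the mean, and 94 to 116 for the lists. A group left with 1 array is assumed to vary like the others. The highest numbers against BMDM came from the fit without peritoneal replicate 1, which drops the pair with the widest spread from the residual.

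No pairing of the arrays by replicate number was seen. Replicate differences correlated at 0.046 (peritoneum and intestine), -0.143 (peritoneum and adipose tissue) and -0.092 (intestine and adipose tissue). The peritoneal difference is also that between the array sets, so pairing is not excluded. With a replicate block the F test gave 9556 and the lists 111. The slide block was not run, because the file names no slides. Signal over background limits what is seen, with 22.6% to 26.4% of probes detected per array.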

Other observations

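The tests in this part were chosen only after the values were seen, apart from the gene lists, which were planned.

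Haemoglobin transcripts were found on most tissue arrays. Hba-a1 was at 15.42 in the spleen, 13.98 in Kupffer cells, 12.24 in the lung, 12.32 and 12.24 on the adipose arrays, 10.22 and 10.10 on the intestinal arrays, 8.10 and 4.77 on the peritoneal arrays and 4.75 in BMDM. Alas2, which red-cell precursors use to make heme, was at 12.14 in the spleen, 8.21 in Kupffer cells and between 4.94 and 6.73 on the other arrays.

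The immediate early list, as a median relative to the mean of the groups, was at 1.40 and 1.42 on the intestinal arrays, 0.85 and 0.97 on the adipose arrays, 0.19 in the lung, 0.15 in Kupffer cells, -0.29 in the spleen, -1.38 in BMDM, and -1.52 and -1.70 on the peritoneal arrays.

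The TGF-beta pathway and retinoid lists passed in 0 of 7 groups each (camera, 0 at an unadjusted p under 0.05; lowest adjusted p = 0.154 and 0.183). The platelet and the eosinophil and mast cell lists also passed in 0 groups (0 at an unadjusted p under 0.05; lowest adjusted p = 0.157 and 0.143), as did the neutrophil list (2 at an unadjusted p under 0.05; lowest adjusted p = 0.078).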
